A study of Mus musculus with 9 samples.

How the data were processed

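RNA was extracted from mouse cortex at E16.5, and libraries were made from 50 ng of total RNA with a kit that captures mRNA, per the labels' protocols. The 9 libraries fall into 3 genotypes of 3, which the design text calls biological replicates, and all 9 have the same batch label. The submitters' processing notes name cutadapt, Bowtie2 2.4.4 and STAR 2.7.9a and the builds mm10 and mm9, with no roles, so the counting method and annotation are not given in the sources used here.

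The sources used here were the authors' deposited comparison tables for the deletion and the knock-in, each against control. Per the file headers and notes, the authors made log2 fold changes and their standard errors (log2 scale) and a Wald score per gene with DESeq2. The deposited p-value columns are the raw p and the Benjamini-Hochberg adjusted p of the authors. The deposited baseMean is a signal, the authors' mean normalised count over all samples, and was equal in both tables for all 39184 genes listed in both. The deposited columns headed FPKM, with names of control, deletion and knock-in libraries, were other than that unit: in each of 4 tables every value equalled baseMean times a random number. Within a tolerance of 1e-09, 235530 of 235530 deletion values and 242196 of 242196 knock-in values equalled baseMean times successive draws of R's normal generator with mean 1, SD 0.1 and seed 42, and 0 did with the next seed. The shorter lists gave 354 of 354 and 390 of 390. These columns hold no measurement of a library and were not used, so values per library, their spread and the depth of each library are not reported here.

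The deposited columns were then checked against each other, with a relative tolerance of 1e-06 on log2 fold change and 1e-04 on log10 p. They disagreed for 22 and 25 log2 fold changes and for 4 and 930 p-values in the deletion and the knock-in. Before the data were examined, the plan was to take the authors' adjusted p as the main result where comparisons alone were held. Because of these disagreements the main values were instead taken from the deposited statistic and SE: log2 fold change as their product, a 2-sided normal p of the statistic, and Benjamini-Hochberg adjustment over the genes that have a deposited adjusted p, 18952 in the deletion and 21222 in the knock-in. This was chosen after the data were seen, and the deposited values are given as alternatives. A change made alike to the statistic, SE and fold change of a gene could not be detected. The statistic was that of the full table of each comparison. The authors' shorter lists hold another one for some genes, as given below. The threshold was an adjusted p of 0.05. The SE had a median of 0.14 in the deletion and 0.16 in the knock-in.

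The groups, lists, tests and alternatives were fixed before the data were examined. The named genes were, per comparison and among genes past the threshold with a baseMean of at least 50, the 8 largest rises and falls, then the 4 smallest p-values in each direction not yet named, members of the gene lists past the threshold, up to 12 genes past it in both comparisons, and Etv5 and Tra2b in any case. Unnamed gene models and pseudogenes were passed over. A gene chosen by these rules is not reported here. The 31 gene lists covered cell types of the cortex and of adjoining tissues, signalling, stress, synapse, splicing, sex-linked and mitochondrial genes and the Etv5-Tra2b neighbourhood. Each list was tested on the Wald statistics with the pre-ranked camera test of limma 3.58.1 in R 4.3.3, with a preset correlation of 0.01 between genes and adjustment over the lists of a comparison. The difference between comparisons was the difference of log2 fold changes over the root of the summed squared SEs. Chromosomes were compared with Fisher's exact test, adjusted over chromosomes. Gene positions and types came from the GENCODE annotation of mm10, in which 18652 and 20764 of the tested genes were found. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

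The steps were tested on simulated data. With 200 changed genes among 18952 and the real SEs of the deletion, 46.3% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 98.5% of those changed 4-fold were recovered, with 5 false among 150 calls. With the 21222 genes of the knock-in these were 47.8%, 76.1% and 90.9%, with 3 false among 146 calls. The check of columns found 20 of 20 altered fold changes and 50 of 50 altered p-values in each simulated table. The list test was tested on simulated standard normal statistics of 18937 genes and recovered a list shifted by 1.5 in 92 of 100 runs. Genes were drawn independently in these simulations, so correlation between genes was not tested. The real statistics also spread more widely than those simulated for the list test, as given below. Alternatives were thresholds of 0.1 and 0.01, a fold of at least 1.5, a baseMean of at least 50, adjustment over every gene with a p, a preset correlation of 0.05, a rank-based list test, and, chosen after the data were seen, the deposited values, the deposited knock-in adjusted p multiplied by 1000 and the knock-in without Y chromosome genes.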

Results

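Gene expression was measured by RNA sequencing in the cortex of mouse embryos that differed at HAR1984. A human accelerated region such as HAR1984 is a stretch of DNA that is conserved among vertebrates and changed unusually fast on the human lineage, and the series treats it as an enhancer. Control embryos had the mouse sequence on both alleles (Mm/Mm), knock-in embryos had 1 human and 1 mouse allele (Hs/Mm), and deletion embryos lacked the element on both alleles (del/del). Each genotype had 3 libraries, and the labels place all 9 at E16.5, late in cortical neurogenesis, except deletion replicate 3, whose tissue label reads E16.6. The labels describe the tissue as cortex and the cell type as neural progenitors. Results per gene were analysed here as 1 comparison of each altered genotype with the control. The deposited mean normalised counts, summed over genes, came to 44.3 in units of 1e+06 reads, and the depth of each library is unknown. Every log2 fold change below is the product of the deposited Wald statistic and its standard error (SE), unless the authors' deposited table is named, and rests on 3 libraries per group.

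The first question was what changes in the cortex when HAR1984 is absent. In deletion embryos, transcripts of the ventral forebrain fell and transcripts of the meninges and blood vessels rose. Tac1, which encodes the substance P precursor of striatal neurons, fell by 3.10 on the log2 scale (SE 0.80, adjusted p = 0.0203). The homeobox genes Dlx5 (-1.06, SE 0.25), Dlx6 (-1.98, SE 0.55), Dlx1 (-0.75, SE 0.20) and Dlx2 (-0.77, SE 0.18), regulators of GABAergic neurons born in the ganglionic eminences, were also lower. Among the rises were Lyve1, a hyaluronan receptor of lymphatic endothelium and perivascular macrophages (1.26, SE 0.20, adjusted p = 9.12e-07), and Vwf, the clotting factor made by endothelial cells (1.13, SE 0.18, adjusted p = 9.12e-07). In all, 185 of 18952 genes tested passed an adjusted p of 0.05 by the Wald test, 95 higher and 90 lower, and 1800 genes had an unadjusted p under 0.05 where 947.6 would be so by chance.

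Among genes past the threshold with a mean normalised count of at least 50, the largest fall in the deletion was that of Prdm12, a transcriptional regulator known from sensory neurons, at -3.79 (SE 0.70, adjusted p = 6.23e-05). Aldh1a3, a retinoic acid-synthesising enzyme of the lateral ganglionic eminence, fell by 2.7 (SE 0.43, adjusted p = 9.79e-07), and Fgf15, a secreted growth factor, fell by 2.48 (SE 0.41, adjusted p = 1.64e-06). Nkx2-3 (-1.95, SE 0.49), Nrsn2 (-1.78, SE 0.31) and the guidance cue Ntn1 (-1.66, SE 0.41) completed the large falls. Among the smallest p-values were those of Pbx3 (-1.07, SE 0.15, adjusted p = 7.10e-09) and Meis1 (-0.93, SE 0.15, adjusted p = 9.79e-07), homeodomain factors that act together, and of the Sox1 overlapping transcript Sox1ot (-1.05, SE 0.17) and Fstl5 (-0.60, SE 0.10). Large rises by the same rule were those of Itih2 (1.5, SE 0.38), the organic anion transporter Slc22a6 (1.38, SE 0.27), the transcription factor gene Six2 (1.33, SE 0.27), Asgr1 (1.28, SE 0.37), Fcna (1.26, SE 0.31) and the aminopeptidase gene Enpep (1.26, SE 0.29). Spon2 (1.23, SE 0.22) and the extracellular matrix gene Fbn2 (0.72, SE 0.14) had smaller rises with adjusted p of 4.68e-05 and 1.60e-04.

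Cell type lists moved as groups in the deletion. All 11 meningeal genes were above control, with a median of 0.80, and the list rose (camera adjusted p = 2.94e-13). Of these, 4 passed over all genes, namely Col1a2 (1.01), Slc6a13 (1.05), Foxc1 (0.82) and Fn1 (0.75), and 10 when adjusted over the list alone. All 12 endothelial and pericyte genes were above control (median 0.47, adjusted p = 2.70e-13), with Flt1, a VEGF receptor, at 0.65 and Vtn at 0.86 past the threshold, and 11 adjusted over the list alone. Hypoxia and glycolysis genes rose (median 0.16, adjusted p = 2.99e-06), although only Adm, the hypoxia-inducible peptide gene, passed alone, at 0.99 (SE 0.23). Adjusted over the list alone, 5 of the 15 passed. Microglial genes (median 0.44, adjusted p = 2.73e-04), upper layer neuron genes (median 0.28, adjusted p = 0.0118) and interferon response genes (median 0.31, adjusted p = 0.0292, and 0.0606 with a preset correlation of 0.05) also rose, with 0 members past the threshold over all genes. Adjusted over the list alone, 1 microglial gene, 0 upper layer genes and 1 interferon response gene passed.

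The interneuron list fell (median -0.61, adjusted p = 3.03e-08). Its 5 members past the threshold over all genes were the Dlx genes above and Dlx6os1 (-0.95, SE 0.20), an RNA transcribed beside Dlx5 and Dlx6, and 9 of 16 passed when adjusted over the list alone. The values of Sst (-0.10, SE 0.49) and Lhx6 (-0.09, SE 0.24), markers of migrating cortical interneurons, did not pass. The striatum and subpallium list fell with a median of -1.42 (adjusted p = 1.80e-06). Tac1 and Gsx2, a patterning factor of the lateral ganglionic eminence (-1.51, SE 0.42), passed over all genes, and 9 of 13 passed when adjusted over the list alone. Diencephalic genes fell with 5 of 11 members tested (median -0.36, adjusted p = 2.73e-04). Smaller falls of whole lists were those of the cell cycle (median -0.24, 20 of 20 below control, adjusted p = 2.90e-04), mitochondrially encoded transcripts (median -0.16, adjusted p = 2.73e-04), SR splicing factors (median -0.11, 12 of 12 below, adjusted p = 4.88e-04), radial glia (median -0.15, adjusted p = 0.00302) and erythroid cells (median -0.23, adjusted p = 0.00293). The only member of these 5 lists past the threshold over all genes was Bpgm, the bisphosphoglycerate mutase of red cells, at -0.27 (SE 0.08). Adjusted over the list alone, 2 erythroid and 1 diencephalic gene passed, and 0 of the cell cycle, mitochondrial, splicing and radial glia lists.

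The other 17 lists gave adjusted p between 0.0714 and 0.903 in the deletion. They were the intermediate progenitors, newborn neurons, deep layer neurons, Cajal-Retzius cells, oligodendrocyte and astrocyte lineage, choroid plexus, hippocampus and cortical hem, FGF-ERK targets and ETV factors, Notch pathway, Wnt targets, immediate early genes, integrated stress response, heat shock, p53 targets, synapse, sex-linked genes and the Etv5-Tra2b neighbourhood. Among these, the median and mean lay on opposite sides of 0 for newborn neurons, FGF-ERK targets, immediate early genes and heat shock. Called genes were more frequent than elsewhere on chromosome 6, with 22 of 915 tested genes against 9.08 expected (Fisher's exact test, 2-sided, adjusted p = 0.00246), Dlx5, Dlx6, Dlx6os1 and Tac1 among them. These named genes start between positions 6820189 and 7554879, and Dlx6os1 overlaps Dlx6. The test takes genes as independent, so it may count a regional change more than once. With genes called at an adjusted p of 0.1 the same test gave 0.155. Library values that could give a correlation between genes were not used here, so list tests rest on a preset correlation of 0.01. In both comparisons these tests take genes as the units, and their p-values do not measure the spread between libraries. A correlation within a list above the preset would make its p-value too small. With a preset of 0.05, 13 of the 14 lists past the threshold held, and the interferon response did not (adjusted p = 0.0606).

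**Figure D1:**
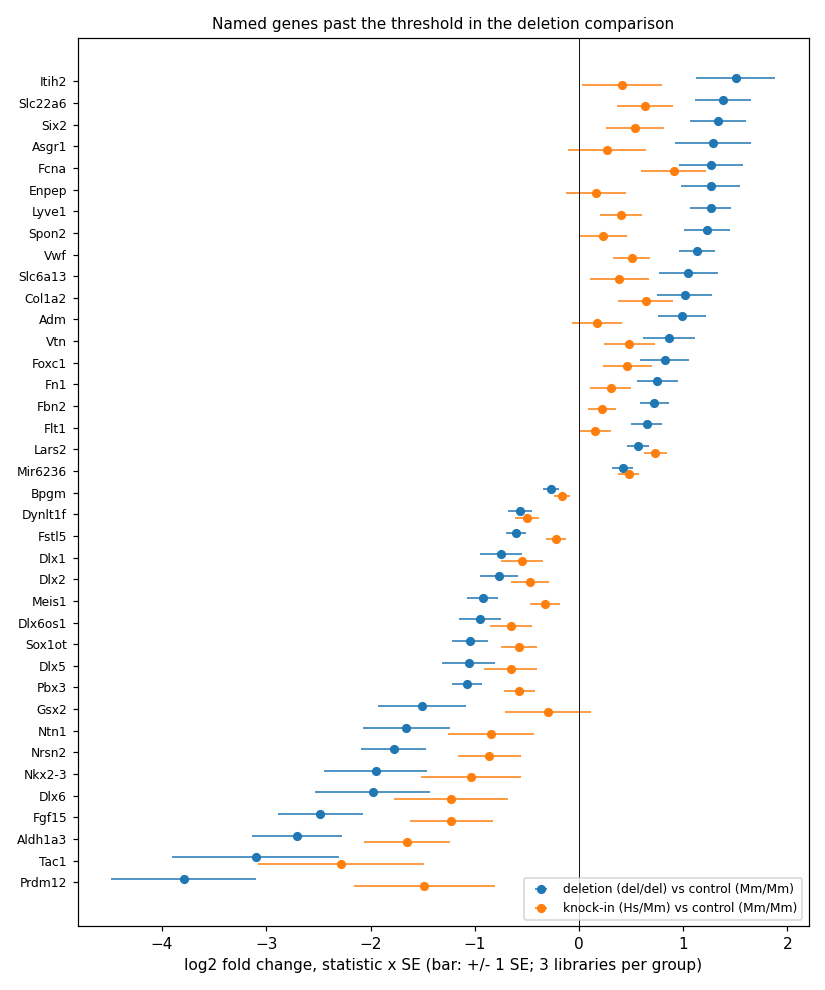
Log2 fold change (horizontal axis, statistic times SE) of named genes past the threshold in the deletion comparison, with the deletion in blue and the knock-in in orange, each against control; bars are 1 SE either side, from 3 libraries per group. Prdm12 (-3.79) and Itih2 (1.5) are at the ends of the blue series.

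The second question was what 1 human allele does to the same tissue. Knock-in embryos had few genes past the threshold, 29 of 21222 tested, of which 19 were higher and 10 lower, while 1468 genes had an unadjusted p under 0.05 where 1061.1 would be so by chance. Lars2, the mitochondrial leucyl-tRNA synthetase gene, rose by 0.73 on the log2 scale (SE 0.11, adjusted p = 9.86e-08), followed by Mir6236 (0.48, SE 0.10, adjusted p = 0.00364) and Klhl25, an adaptor of a ubiquitin ligase (0.31, SE 0.06, adjusted p = 3.12e-04). Mir6236 is annotated as a miRNA gene, yet had a baseMean of 11148 in libraries that capture mRNA, so the origin of its reads is uncertain. The smallest p was that of Gm15564, an unnamed gene model (0.83, SE 0.11, adjusted p = 8.18e-10), chosen after its values were seen. Lars2 and Gm15564 rose alongside Mir6236 in both comparisons. Whether their reads have the same origin as those of Mir6236 was not examined, so their rises are uncertain too. Aldh1a3 fell by 1.65 (SE 0.41, adjusted p = 0.0487), Cyp4x1, a cytochrome P450 gene, fell by 0.82 (SE 0.20, adjusted p = 0.0442) and the dynein light chain gene Dynlt1f fell by 0.50 (SE 0.11, adjusted p = 0.0147).

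The largest falls in the knock-in were on the Y chromosome. The sex of the embryos is not given in the sources used here. Eif2s3y, Ddx3y, Kdm5d and Uty fell together, as fewer or no male embryos in the knock-in group would give. These falls are therefore not read as an effect of the allele, though the sex of each embryo is unknown. The values of Eif2s3y and Uty leave the knock-in libraries with hardly any reads of these genes, unlike the control. A difference in sex therefore goes with genotype across the knock-in comparison, and its share in genes outside the Y chromosome was not tested. Eif2s3y had -27.20 (SE 3.91, adjusted p = 3.58e-08) and Ddx3y -10.89 (SE 2.68, adjusted p = 0.0442), and Kdm5d and Uty, chosen after their values were seen, had -11.30 (SE 3.02, adjusted p = 0.0783) and -26.20 (SE 3.66, with no adjusted p). Values near -27 are of the size such fits give when a group has hardly any reads, and are not measured ratios. In the deletion, Eif2s3y had -1.26 (SE 3.73) and Ddx3y -1.38 (SE 2.54). Xist, which coats the inactive X chromosome and was likewise chosen after its values were seen, had 1.46 (SE 2.44) in the knock-in and 1.41 (SE 2.44) in the deletion. Processed copies made up most of the rises: 14 of the 19 genes were annotated as pseudogenes, 73.7% against 14.6% of the genes tested (Fisher's exact test, 2-sided, p = 1.07e-08). In the deletion 10 of the 95 rises were pseudogenes. Pseudogenes can share reads with their parent genes, so their values are uncertain.

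Knock-in lists moved mostly without single genes past the threshold. The interneuron list fell (median -0.50, 15 of 16 below control, adjusted p = 7.12e-10), with 0 members past the threshold over all genes and 7 when adjusted over the list alone, Gad1 (-0.67, SE 0.24) and Gad2 (-0.67, SE 0.22), the GABA-synthesising enzymes, among them. In the authors' deposited table Gad1 (1.67), Dlx1 (1.55) and Dlx2 (0.47) of this list have the opposite sign in the knock-in. The fall of this list therefore rests on the full-table statistics of these genes. Synapse genes fell (median -0.28, 15 of 16 below, adjusted p = 1.45e-06), as did striatum and subpallium genes (median -0.86, adjusted p = 2.82e-04), mitochondrially encoded transcripts (median -0.10, adjusted p = 3.84e-04) and the sex-linked list (adjusted p = 3.11e-09, and 0.0564 with a rank-based test). Endothelial and pericyte genes (median 0.31, adjusted p = 4.05e-06) and meningeal genes (median 0.46, adjusted p = 3.63e-05) rose. So did the Notch pathway (median 0.22, 14 of 14 above, adjusted p = 2.82e-04), the cell cycle (median 0.21, 20 of 20 above, adjusted p = 2.82e-04), intermediate progenitors (median 0.21, 12 of 12 above, adjusted p = 6.24e-04) and radial glia (median 0.18, adjusted p = 0.00500). The Notch list shares Notch1, Hes1 and Hes5 with radial glia, and Dll1 and Dll3 with intermediate progenitors, so these rises are not separate results. Erythroid genes rose too (median 0.25, adjusted p = 5.56e-04), and the embryonic globin gene Hbb-y, which passed when adjusted over the list alone, had 2.41 (SE 0.83). Hypoxia and glycolysis (median 0.16, adjusted p = 0.00195), interferon response (median 0.36, adjusted p = 0.00199) and microglial genes (median 0.28, adjusted p = 0.00389) completed the rises. Adjusted over the list alone, 3 sex-linked, 3 erythroid, 1 synapse and 1 hypoxia gene passed besides the 7 interneuron genes, and 0 genes of the striatum, mitochondrial, endothelial, meningeal, Notch, cell cycle, intermediate progenitor, radial glia, interferon and microglial lists.

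The other 16 lists gave adjusted p between 0.141 and 0.995 in the knock-in. They were the newborn neurons, deep layer neurons, upper layer neurons, Cajal-Retzius cells, oligodendrocyte and astrocyte lineage, choroid plexus, diencephalon, hippocampus and cortical hem, FGF-ERK targets and ETV factors, Wnt targets, immediate early genes, integrated stress response, heat shock, p53 targets, SR splicing factors and the Etv5-Tra2b neighbourhood. Median and mean lay on opposite sides of 0 for the deep layer, upper layer and splicing factor lists. All 15 lists past the threshold held at a preset correlation of 0.05. On the Y chromosome 2 of 11 tested genes were called, Eif2s3y and Ddx3y (Fisher's exact test, 2-sided, adjusted p = 0.00226).

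**Figure D2:**
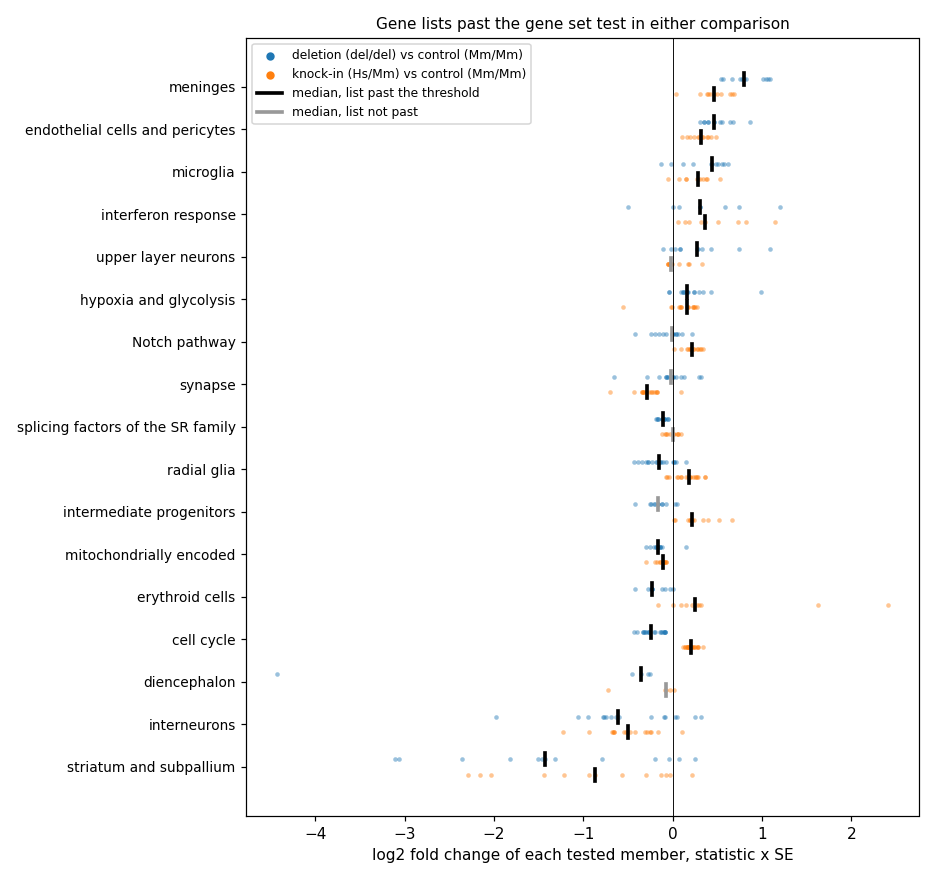
Log2 fold change (horizontal axis, statistic times SE) of each tested member of the gene lists past the threshold in either comparison, sex-linked genes left out; blue points are the deletion and orange points the knock-in, each against control, and bars are list medians, black where the list passed. Cell cycle medians are -0.24 in the deletion and 0.21 in the knock-in.

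Etv5, an ETS-family transcription factor gene that responds to FGF signalling, and Tra2b, a splicing factor gene, were fixed for report in any case before the data were examined. They are neighbours on chromosome 16 of mm10, with Etv5 (ENSMUSG00000013089) at 22381309 to 22439719 and Tra2b (ENSMUSG00000022858) at 22244549 to 22266005. Etv5 differed from control by -0.05 (SE 0.16, adjusted p = 0.988) in the deletion and by 0.16 (SE 0.16, adjusted p = 0.873) in the knock-in. Tra2b differed by -0.16 (SE 0.09, adjusted p = 0.577) and by 0.07 (SE 0.09, adjusted p = 0.917). In the authors' deposited table the log2 fold changes of Etv5 are -1.47 in the deletion and 1.36 in the knock-in, with adjusted p of 0.0398 and 1.75e-05. Those of Tra2b in the authors' deposited table are -1.59 and 1.57, with adjusted p of 0.0475 and 1.54e-05. None of these 4 deposited values equals its own statistic times its own SE in the full table. The authors' shorter list of genes in common holds other statistics for these genes. There Etv5 has -1.297 in the deletion, where the full table has -0.297, and 1.601 in the knock-in, also larger than in the full table. Tra2b has 1.761 there in the knock-in, where the full table has 0.761, and the same statistic in the deletion. The recomputed values above rest on the full tables alone. Of the 26 tested genes within 1 Mb of Etv5, including Etv5 itself, 0 passed the threshold in either comparison, with smallest adjusted p of 0.572 in the deletion and 0.696 in the knock-in.

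The next question was which changes the genotypes have in common. Lars2, Mir6236 and the unnamed gene model Gm15564 rose, and Aldh1a3 and Dynlt1f fell, in both comparisons. Dynlt1, Dynlt1a and the pseudogene Dynlt1-ps1, chosen after their values were seen, passed in the deletion (-0.97, -0.54 and -0.65). In the knock-in they had -0.73, -0.45 and -0.43, and of these genes only Dynlt1-ps1 passed. Reads shared between these similarly named genes were not examined, so the value of Dynlt1f is uncertain. The reads of Mir6236 are of uncertain origin, and the rises of Lars2 and Gm15564 are uncertain with it, as described above. In all, 17 genes passed the threshold in both among the 18928 genes tested in both, 11 higher in both, 6 lower in both and 0 in opposite directions. Of the 17, 11 were annotated as pseudogenes, whose values are uncertain as described above. Independent lists of these sizes would share 0.274 genes, 0.0954 higher and 0.0428 lower. Both comparisons use the same 3 control libraries, so they are not independent. The Wald statistics of the 2 comparisons had a covariance of 0.629 across genes, against 0.501 in unchanged groups simulated with shared controls, a difference of 0.128, and their correlation was 0.465 against 0.50 simulated. The statistics had SDs of 1.20 in the deletion and 1.13 in the knock-in, against 1 simulated, and a wider spread alone raises a covariance. The sign was the same for 62.1% of genes, against 66.6% simulated. The control libraries could not be split, so part of the overlap may come from them.

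The genotypes were also set against each other, as the knock-in minus the deletion. By that test of the difference 1 gene of 18928 passed, Eif2s3y of the Y chromosome (-25.94, SE 5.40, adjusted p = 0.0292), for which the sex of the embryos is open as above, and 378 genes had an unadjusted p under 0.05. The test leaves out the covariance from the shared controls, so its SE is too large, and 378 is fewer genes than chance would give. With a shared covariance of 0.5 of the product of the SEs, 9 genes passed, among them Hbb-bt, an adult globin gene, and Lyve1 and Spon2, of which Hbb-bt was chosen after its values were seen.

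The deposited log2 fold changes, statistics and p-values disagreed with each other for a set of genes that included regulators of forebrain development. In the deletion 22 genes had a deposited log2 fold change other than the statistic times the SE, and in the knock-in 25 had one. All 22 and 23 of the 25 were in the authors' deposited lists of genes past an adjusted p of 0.05 and a log2 fold change of 1.3 in size. Within a tolerance of 1e-06, the deposited value was the larger in size for 22 of 22 and for 22 of 25, the other 3 differing in sign alone, and 8 genes in each comparison had a gap of 1. In the deletion 18 of the 22, Meis1, Dlx2 and Pbx3 among them, still passed the threshold from their statistics, and Etv5, Tra2b, Gli1 and Gli2 did not. In the knock-in 0 of the 25 passed, and 9 had opposite signs: Dlx1, Dlx2, Foxp2, Gabra3, Gad1, Nova1, Npas4, Shh and Sufu. The deposited statistics also differed between tables. The authors' lists past both criteria held another statistic than the full tables for 3 deletion and 10 knock-in genes. Their list of genes in common did so for 3 and 6. There the knock-in statistic of Nova1 is 2.76, where the full table has -2.76, so its direction is not settled. Shh, a ventralising morphogen gene, is 1.44 in the authors' deposited table, where its statistic times SE gives -1.14 (SE 0.80). Its knock-in statistic is -1.43 in the full table and 1.43 in the list of genes in common, so its direction is not settled either. These genes were named after their values were seen.

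P-values differed as well. In the knock-in 930 genes of the authors' deposited table had an adjusted p under 0.05, and for all 930 the deposited p was not the p of the deposited Wald statistic. For 923 of them it was lower by a factor of 1000 exactly, within the tolerance used, and the largest p given by a statistic among these was 0.0268. In the deletion the deposited adjusted p called 196 genes, and the 4 with a p unlike that of their statistic were Etv5, Tra2b, Gli1 and Gli2. Deposited adjusted p were over 5% away from a Benjamini-Hochberg adjustment of the deposited p for 6 deletion and 43 knock-in genes. In the deletion these were the same 4 and Gbx2 and Shh, whose deposited p was that of their statistics. Shh has an adjusted p of 0.0170 in the authors' deposited table, where the adjustment of its deposited p gives 0.171. Of the authors' deposited lists, 34 of 59 deletion genes and 7 of 65 knock-in genes met both criteria when recomputed from statistic and SE. The authors' deposited list of genes in common held 15 genes, of which 3 passed the recomputed threshold in both comparisons. How these differences arose was not examined.

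**Figure D3:**
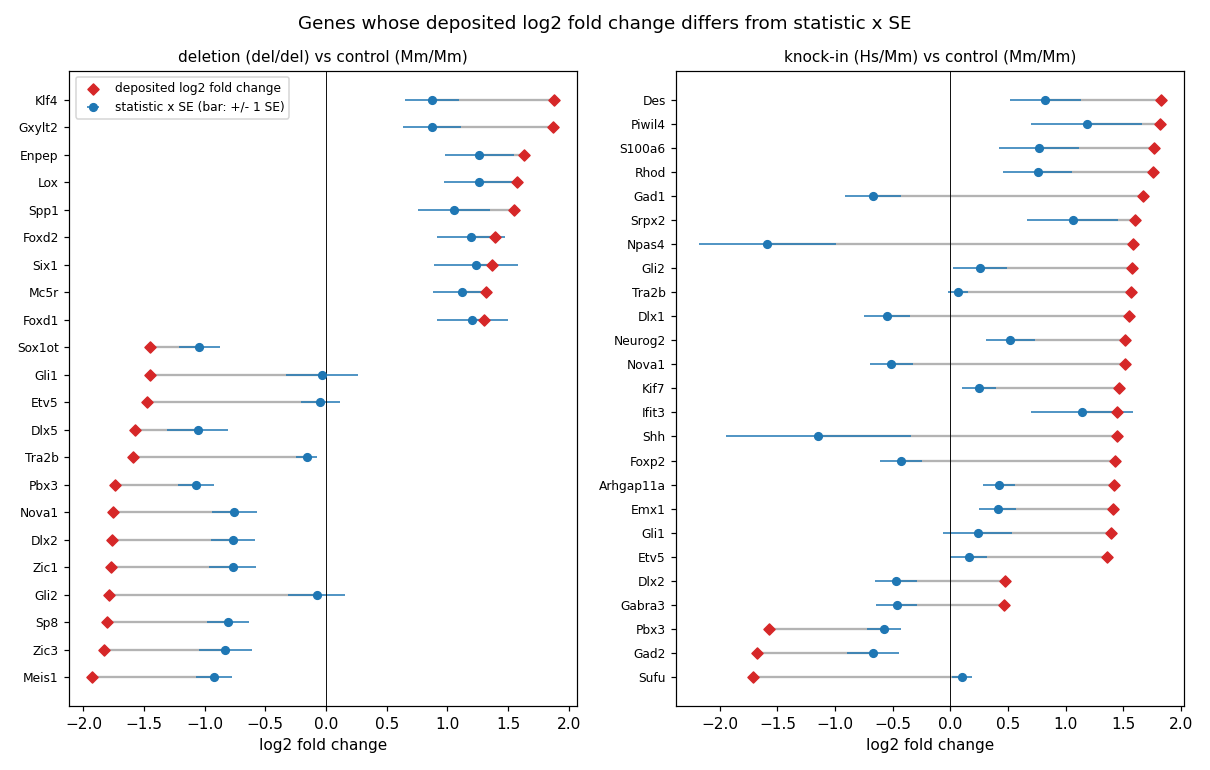
Log2 fold change (horizontal axis) of the 22 deletion genes and the 25 knock-in genes whose deposited value differs from statistic times SE; red diamonds are values of the authors' deposited table and blue points are statistic times SE, with bars of 1 SE either side. Etv5 is at -1.47 deposited and -0.05 recomputed in the deletion, and at 1.36 and 0.16 in the knock-in.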

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

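The list tests of the knock-in minus deletion difference were chosen after the lists of each comparison were seen, as were all tests below except those on the second gene lists of the first pattern and on ribosomal protein pseudogenes. The comparison of pseudogenes with their parent genes was also chosen after their values were seen.

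Proliferation and progenitor lists separated the genotypes, and the results of this paragraph were selected because the genotypes differed by a test of the difference itself. The camera test of the difference put the cell cycle list higher in the knock-in than in the deletion (adjusted p = 1.98e-12, median difference 0.44), as it did radial glia (2.69e-08), intermediate progenitors (3.24e-07), the Notch pathway (3.26e-05), erythroid cells (4.43e-10), the diencephalon (0.00197) and SR splicing factors (0.00221). Lower in the knock-in than in the deletion were the synapse (adjusted p = 3.75e-05), the meninges (0.00185), endothelial cells and pericytes (0.00468), upper layer neurons (0.0496, and 0.107 with a preset correlation of 0.05) and the sex-linked list (8.98e-08). With that preset the cell cycle list gave 1.23e-07. These tests take genes as the units, so their p-values do not measure the spread between libraries of a genotype. The Notch list shares genes with the radial glia and intermediate progenitor lists, as given above, so their results are not separate. Of the 20 cell cycle genes, 0 passed alone in either comparison. Of single genes, Eif2s3y of the Y chromosome differed by -25.94 on the log2 scale, a fitted value of the size given when a group has hardly any reads and not a measured ratio. The sex of the embryos is not given in the sources used here, so neither Eif2s3y nor the sex-linked list separates genotype from sex. The other lists of this paragraph may carry a difference in sex too, which was not tested.

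The first pattern weighed was the rise of meningeal and vascular genes with the fall of ventral forebrain genes in the deletion: if a lower share of the main cell type had raised all other types alike, erythroid genes would have risen too, and they fell (median -0.23). That fall was seen before the prediction was written. Blood left in a sample also moves erythroid genes, so their fall does not exclude a lower share. More meningeal and vascular tissue in the dissected samples may account for the rise: 24 of 24 further meningeal and vascular genes, listed before their values were seen, were above control, with a median of 0.54. Less subpallial tissue may account for the fall: of 11 further subpallial genes, listed in the same way, 9 were below control, with a median of -0.52. The lists at first also held 5 and 2 genes already seen among the genes past the threshold, and these were removed after a first run, in which 29 of 29 were above control (median 0.65) and 11 of 13 below (median -0.90). The same lists had medians of 0.32 and -0.45 in the knock-in, on the same side of the shared controls, and an effect of the genotype on these cell types stays open and untested.

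The second pattern was the cell cycle, lower in the deletion and higher in the knock-in. Chance values of the shared controls cancel in the knock-in minus deletion difference, so they do not account for its median of 0.44, which follows from the opposite directions of the lists themselves. A different share of cycling progenitors is a candidate explanation, since the radial glia list moved with the cell cycle in both, with medians 0.34 apart. Younger knock-in embryos are another, with a median of 2.02 for the embryonic globins Hbb-y and Hba-x (SE 0.83 and 0.80) and a fall of synapse genes. Whether deletion embryos were older could not be told, since the same globins had a median of -0.24 with SEs of 0.83 and 0.80, and an effect of the genotypes on proliferation stays open as well.

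The third pattern was the share of pseudogenes among the knock-in rises, which was not selected by a test of the difference. Whether reads shared with ribosomal protein genes account for it could not be told. All 168 tested pseudogenes named after ribosomal protein genes, some already seen one by one, had a median of 0.19. That is near the 0.15 of the 82 ribosomal protein genes. The 14 pseudogenes among the rises had a median of 0.61. The 6 of them so named rose by a median of 0.44 more than their parent genes (median SE 0.17). The 14 and the 6 were picked for passing the threshold, which raises their values, so this excess cannot decide. Parents of the unnamed gene models among the 14 were not looked up. Whether chance values of the shared controls contribute could not be told either: of 14 unchanged genes with these knock-in statistics 13.93 would be above control in the deletion and 14 were, and their deletion statistics exceeded 0.5 of the knock-in statistics, the assumed share, by a median of 1.08. No biological explanation was tested for this pattern.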

How the results depend on the processing

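The deposited values and the removal of Y chromosome genes were chosen after the data were seen, and the other settings before. No paired analysis was possible because the deposited results are per gene and the columns named by library hold no library measurement. For the same reason the replicate block, a count test, other scalings and pseudocounts, a fit of all 9 libraries, leaving out each library, other splits of the samples and an estimated correlation were not run. The deletion count of 185 became 308 at an adjusted p of 0.1, 75 at 0.01 and 115 with adjustment over every gene with a p, where more genes were tested. The knock-in count of 29 became 58 and 16 at those thresholds, and 930 by the adjusted p of the authors' deposited table, where 923 p-values are 1000-fold below those of their statistics. Multiplying that adjusted p by 1000 gave 38, and leaving out Y chromosome genes gave 27, which does not remove an effect of sex on other genes. Genes called in both comparisons numbered 31 at 0.1, 5 at 0.01 and 96 by the authors' deposited table. The difference test called 9 genes with a shared covariance, which lowers its SE. Chromosome 6 in the deletion lost its call at a threshold of 0.1 (adjusted p = 0.155), and the cause was not tested. Knock-in log2 fold changes in the authors' deposited table were reversed for Dlx1 (1.55) and Dlx2 (0.47). Of 93 list results, 91 kept their side of the threshold at a preset correlation of 0.05, 89 in the rank-based test and 93 with a baseMean of at least 50, none with a change of direction among those past it. Of 54 results for named genes, 54 kept their side with a baseMean of at least 50 and 43 with adjustment over every gene with a p, the other 11 no longer passing.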

Other observations

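Oligodendrocyte and astrocyte lineage genes, which as a list did not pass, went both ways in the deletion. Adjusted over the list alone, Sox10 (-1.15, SE 0.34) and Aldh1l1, a marker of astrocytes and late radial glia (-0.66, SE 0.22), were lower, and Pdgfra (0.54, SE 0.19) and Cspg4 (0.45, SE 0.17), which oligodendrocyte precursors share with perivascular and meningeal cells, were higher. None of these 4 passed over all genes, with adjusted p from 0.0707 to 0.220, and they were chosen after their values were seen. In the diencephalon list Gbx2, a transcription factor gene of the thalamus, had -4.43 (SE 1.29, adjusted p = 0.0564) in the deletion and -0.72 (SE 1.09) in the knock-in, while Barhl2, Lhx9, Slc17a6 and Tcf7l2 had values between -0.46 and -0.26 in the deletion.

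Of 82 ribosomal protein genes, 71 were above control in the knock-in (median 0.15) and 58 in the deletion (median 0.09), with 0 called in either. They were not tested as a list, and since both comparisons use the same 3 control libraries, the agreement between them is not evidence of a common change.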
